A study of Mus musculus with 10 samples.

How the data were processed

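Expression was measured on 10 Affymetrix Mouse Genome 430 2.0 arrays, hybridised with biotin-labelled cDNA that was amplified (NuGEN FL-Ovation) from total RNA of sorted, activated and retrovirally transduced mouse CD4+ T cells from spleen. The authors processed the arrays with Affymetrix Expression Console, and the deposited values are an intensity per probe set and array on a linear scale. The summary method, its version and the scaling are not given in the sources used here. Medians differed between arrays, so the values were not treated as scaled to a common level. Nothing in the labels says that the replicates came from separate animals or cultures, so p-values measure only the spread between these arrays.

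Groups were taken from the sample titles and the numbered sample descriptions. There were 5 groups of 2 arrays. The descriptions abbreviate the source of 4 arrays as D_S, which was read here as DEREG/Scurfy because the protocol names that strain. The strain field gives DEREG on a Balb/c background for all 10 arrays, so this remains a reading of the labels.

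The table held 45101 probe sets, of which 64 were control probe sets. A single gene symbol was attached to 34958 probe sets, several symbols to 932 and no symbol to 9211. Each of 18194 genes was represented by its probe set with the highest mean over the 10 arrays. Intensities were converted to log2 after adding 16, with no further normalization. Genes above the array median on at least 2 arrays were kept, which left 11319 genes. The signal of an array limits precision near the background, and the small number of arrays limits it everywhere.

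Group differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust options) over all 10 arrays. That left 5 residual degrees of freedom, to which the empirical Bayes prior added 4.09, with a prior SD of 0.342 on the log2 scale. p-values were adjusted by Benjamini-Hochberg over all genes within a comparison, and a gene was called at an adjusted p under 0.05. Differences are log2 values with the standard error (SE) of the fit, and all p-values are two-sided. Replicate numbers were not used as a block.

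The comparisons were Treg against Tconv mock, scurfy GFP+ mock against Tconv mock, Foxp3-labelled against mock arrays within each kind of starting cell, the difference between those 2 effects, the scurfy mock, scurfy Foxp3 and Tconv Foxp3 groups against Treg, and scurfy Foxp3 against Tconv Foxp3. Genes called in Treg against Tconv mock were carried into 3 comparisons that use none of those 4 arrays. In comparisons that share the Tconv mock arrays, 100 simulations of unchanged groups gave the correlation that sharing produces.

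Gene lists were tested with camera from limma, first with its preset inter-gene correlation of 0.01 and then with an estimated correlation, adjusted over the lists within a comparison. camera compares a list with all other genes. The 26 lists were Treg surface and effector molecules, Treg-related transcription factors, genes known to carry Treg-specific demethylated regions, effector T cell cytokines, Th1 and cytotoxic genes, Th2 genes, Th17 genes, follicular helper genes, naive and memory T cell genes, co-inhibitory receptors, TCR-induced early genes, cell cycle, interferon-induced, glycolysis, cholesterol synthesis, amino acid stress and heat shock genes, chemokine receptors and homing, pan T cell genes, sex-linked genes, and markers of CD8 T cells, NK cells, B cells, myeloid cells, mast cells and basophils, and red blood cells. Some genes stand in several lists, for example Il10, Ctla4, Ccr8 and Klrg1.

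Named genes followed a rule. In each comparison it took, among called genes whose groups did not overlap, the 12 with the largest upward and the 8 with the largest downward difference, leaving out clone and accession names. It always took Foxp3, Il2ra, Ctla4, Tnfrsf18, Ikzf2, Ikzf4, Il2, Ifng, Il7r and Pde3b. From each list it took up to 4 members with the smallest p, and any called member. Groups, comparisons, lists, this rule and the alternatives were fixed before the data were examined, apart from the alternative without the 2 least correlated arrays, which was chosen after seeing the data. Class II genes and the neighbours of Foxp3 on the X chromosome were also added after other values were seen.

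The pipeline was tested on simulated data with the size of the Treg comparison. It recovered 1 of 67 genes changed by 1 log2 unit, 46 of 67 changed by 2 and 55 of 66 changed by 3. Of 111 calls, 9 were false, and a comparison without changes gave 0 calls. Alternatives were quantile normalization, scaling to a common 75th percentile, pseudocounts of 1 and 64, no filter, a filter at the 75th percentile, the mean of probe sets, each probe set on its own, eBayes with trend and robust options, array weights, a fit on the compared groups alone, a replicate block, and leaving out each array in turn. With 1 array left in a group, its spread was assumed to equal that of the other groups. Python 3.11.15 and matplotlib 3.10.9 prepared tables and figures. Probe sets without a symbol entered a separate fit, and the probe set positions within transcripts were not analysed here.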

Results

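The arrays profiled CD4+ T cells from spleen that differed, by their labels, in where they started and in what virus they received. Starting cells were sorted by a GFP reporter driven by the Foxp3 promoter in DEREG mice. Foxp3 is the transcription factor that defines regulatory T cells (Treg). GFP+ cells from DEREG mice, GFP- conventional T cells (Tconv) from the same strain, and GFP+ cells from DEREG/Scurfy mice, whose Foxp3 gene is mutated, were stimulated through CD3 and CD28. They then received a retrovirus with an NGFR marker, either empty (mock) or carrying Foxp3, and NGFR+ cells were sorted. The sample titles describe GFP+ starting cells as epigenetics(+) and GFP- cells as epigenetics(-). There were 5 groups with 2 arrays each, namely Treg mock, Tconv mock, Tconv Foxp3, scurfy GFP+ mock and scurfy GFP+ Foxp3. Below, the last 2 groups are called scurfy mock and scurfy Foxp3, and every difference is a log2 difference of group means with its SE, from n = 2 arrays per group.

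Median intensity per array ran from 18.8 to 36.5, and the 75th percentile from 124 to 191. The 3'/5' signal ratio of Gapdh ran from 1.75 to 2.24, and that of Actb from 0.917 to 0.986. Correlations across genes with the array's own replicate were 0.976 for Tconv Foxp3, 0.965 for Tconv mock, 0.959 for Treg, 0.953 for scurfy Foxp3 and 0.921 for scurfy mock, where genes are not independent replicates. Scurfy Foxp3 array 1 and scurfy mock array 2 matched each other best, at 0.974. Replicates of the scurfy groups stood further apart than the others, with 1783 genes (15.8%) differing by over 1 log2 unit between the scurfy Foxp3 arrays and 1589 (14.0%) between the scurfy mock arrays. The same count was 1237 for Treg, 690 for Tconv mock and 484 for Tconv Foxp3. The median of all 11319 genes was 0.19 in Treg, 0.22 in scurfy mock and 0.26 in Tconv Foxp3 relative to Tconv mock, and -0.28 in the difference of the Foxp3-vector effects. After quantile normalization these medians were -0.05, -0.02, 0.01 and 0.01, so values are best read relative to those shifts, as camera does.

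Treg against Tconv asked how the natural regulatory cells differed when both kinds of cell had been activated and, by label, given an empty virus. Treg had higher Ikzf2, which encodes the Treg transcription factor Helios (6.75, SE 0.30, adjusted p = 2.8e-05), Foxp3 itself (5.43, SE 0.30, adjusted p = 7.7e-05) and Ikzf4, which encodes Eos (2.38, SE 0.29, adjusted p = 0.0085). Nt5e, the ectoenzyme CD73 that makes adenosine, was higher by 5.32 (SE 0.31), Cpe, carboxypeptidase E, by 6.56 (SE 0.31), and Flicr, a noncoding RNA transcribed beside Foxp3, by 4.97 (SE 0.30). Among Treg surface and effector molecules, Klrg1 (3.59, SE 0.56), Nrp1 (2.60, SE 0.41) and Swap70 (2.00, SE 0.38) were also called. Homing receptors included Gpr15 (3.52, SE 0.40), Cxcr6 (2.39, SE 0.40) and Cxcr4 (1.90, SE 0.36). Lower genes included Grp, gastrin-releasing peptide (-5.74, SE 0.68), the diacylglycerol kinase gene Dgkk (-5.72, SE 0.50), the matrix metalloproteinase Mmp7 (-4.12, SE 0.51) and the cytokine Lif (-3.52, SE 0.52). Il2ra (0.16, SE 0.24), Ctla4 (0.75, SE 0.39), Tnfrsf18 (0.22, SE 0.33) and Il2 (0.00, SE 0.86) were not called.

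Of 26 Treg surface molecules, 4 were higher and 22 were not called over all genes, and 6 were higher within the list, that is, adjusted over it alone (median 0.61, camera adjusted p = 0.033). That list lost its call without Treg array 1 (median 0.73), without Tconv mock array 2 (0.36) and without any of the 4 scurfy arrays (0.61). It also lost the call with array weights, in a fit on the compared groups alone and without the 2 least correlated arrays, each at 0.61. At a common 75th percentile its median was 0.30, and with each probe set on its own 1.18. All 6 genes known to carry Treg-specific demethylated regions were on the positive side, with 3 called over all genes and 3 within the list (median 1.57, adjusted p = 5.7e-06). Th2 genes were lower in Treg, with 12 of 14 negative, 0 called over all genes, and 5 lower and 1 higher within the list (median -1.52, adjusted p = 1.1e-06). Their members Il24 (-4.69, SE 0.94, adjusted p = 0.060) and Il13 (-4.44, SE 1.29, adjusted p = 0.14) were not called singly. The Th2 median was -2.39 without Treg array 2. Chemokine receptors and homing genes were higher (median 1.66, 16 of 19 positive, 3 called, and 9 higher and 1 lower within the list, adjusted p = 0.00044). That median was 1.01 without Treg array 2 and 1.05 without Tconv mock array 2. With each probe set on its own the demethylated-region median was 2.38 and the Th2 median -0.91. B cell markers had 10 of 11 positive members (median 1.05, adjusted p = 0.16) and were not called. Their mean was 5.00 on Treg array 1 and 6.64 on Treg array 2, where class II genes were also higher by 3.77. With an estimated correlation the adjusted p was 0.883 for the Treg surface molecules and 0.34 for the other called lists here.

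Metabolic lists were lower in Treg. Amino acid stress genes had a median of -0.83, with 13 of 16 negative, 0 called over all genes, and 6 lower and 1 higher within the list (adjusted p = 9.3e-07). Cholesterol synthesis genes had a median of -0.71 with 13 of 15 negative and 0 called by either adjustment (adjusted p = 1.1e-06). Effector T cell cytokines had a median of -1.09, with 0 of 17 called and 3 lower within the list (adjusted p = 0.0002), and lost the call at -0.03 without Tconv mock array 2. Naive and memory T cell genes (median 1.04, adjusted p = 0.031) lost theirs without either scurfy Foxp3 array (1.04), Treg array 2 (0.96) or Tconv mock array 1 (1.24). Glycolysis genes (median -0.08, adjusted p = 0.039) lost theirs under quantile normalization (-0.15), without Treg array 2 (-0.03) and without either Tconv mock array (-0.05 and -0.10). The glycolysis median was -0.39 at a common 75th percentile and -0.13 without Treg array 1. Filtering at the 75th percentile or taking the mean of probe sets also ended the naive and memory (1.36 and 0.98) and glycolysis calls (-0.08 and -0.09). Each probe set on its own ended the naive and memory call (0.79) and moved glycolysis genes to -0.03. With an estimated correlation the adjusted p was 0.34 for amino acid stress genes, 0.883 for glycolysis genes and 0.743 for the other lists here.

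In all, limma called 123 genes between Treg and Tconv mock, 100 higher and 23 lower, among 1744 at an unadjusted p under 0.05. All 123 had groups that did not overlap, against 51.6% of all genes and 33.3% by chance. Quantile normalization called 178 genes (103 higher, 75 lower) and the common 75th percentile 172 (98 higher, 74 lower), and 107 calls were shared between the main values and quantile normalization. Leaving out an array gave 17 calls without Treg array 2, 17 without Tconv mock array 2, 45 without Tconv mock array 1, 65 and 67 without a Tconv Foxp3 array, 73 without either scurfy Foxp3 array and 217 without either scurfy mock array. Of 28 called genes named by the rule, 9 kept the call in each of the 10 leave-one-out fits, namely Ikzf2, Cpe, Foxp3, Nt5e, Flicr, Msrb3, Ipcef1, Dgkk and Gpr15.

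**Figure D1:**
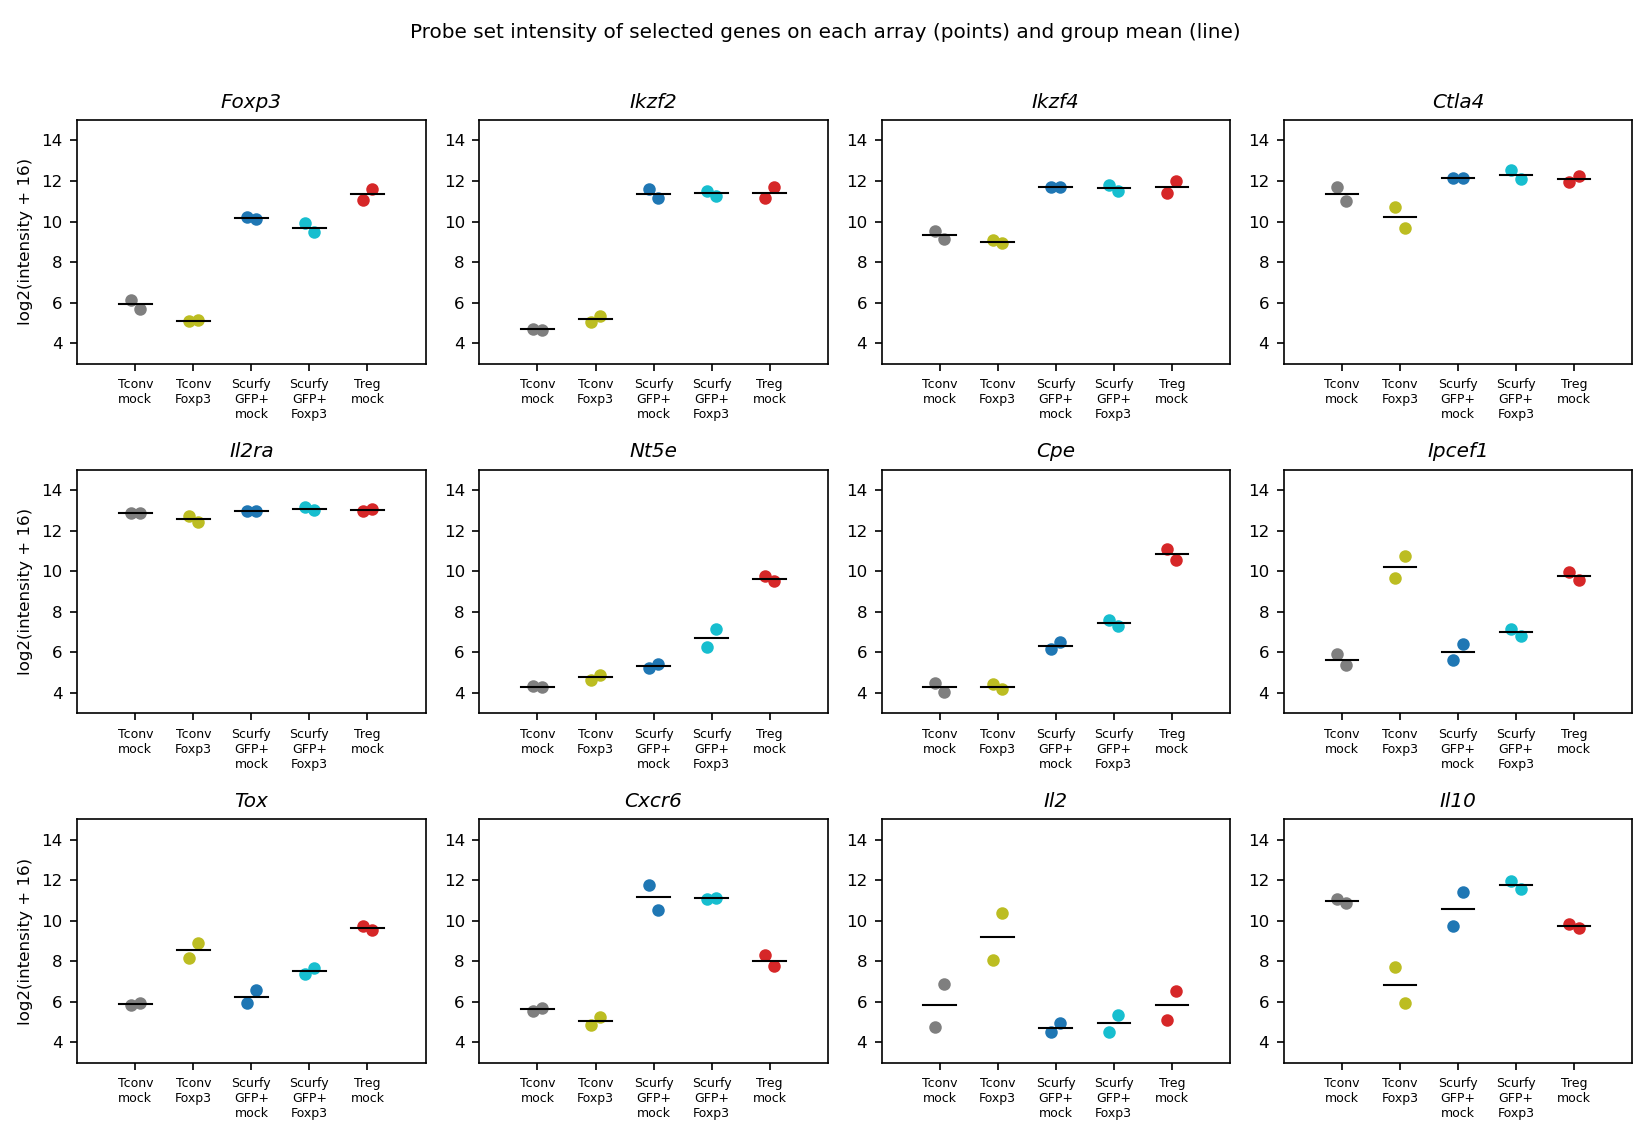
Expression of 12 genes in each array, as log2(intensity + 16) on the vertical axis and the 5 groups on the horizontal axis, with points for arrays and a line for the group mean. Ikzf2 and Foxp3 were high in the 6 arrays from GFP+ starting cells and low in the 4 Tconv arrays, while Nt5e stood highest in Treg.

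Scurfy mock against Tconv mock, also differing in strain, asked which Treg features cells with an active Foxp3 promoter showed without working Foxp3. Ikzf2 was as high as in Treg relative to Tconv mock (6.70, SE 0.30, adjusted p = 2.9e-05), and Ikzf4 was higher by 2.38 (SE 0.29, adjusted p = 0.013). The Foxp3 transcript was higher by 4.28 (SE 0.30) and Flicr by 3.64 (SE 0.30). Cxcr6, the receptor for the chemokine CXCL16, was higher by 5.51 (SE 0.40, adjusted p = 0.00076), and Il1r2, a decoy receptor for interleukin 1, by 3.87 (SE 0.45, adjusted p = 0.013). Rora (4.89, SE 0.51) and Tox2 (4.00, SE 0.38), which encode transcription factors, and Adam19 (5.01, SE 0.65) were also higher. Lower genes included Dgkk (-5.28, SE 0.50), Grp (-5.27, SE 0.68), Mmp7 (-4.01, SE 0.51) and the semaphorin Sema3e (-3.02, SE 0.33). Il2ra (0.09, SE 0.24), Ctla4 (0.80, SE 0.39), Tnfrsf18 (0.26, SE 0.33) and Ifng (2.96, SE 0.85, adjusted p = 0.20) were not called.

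Demethylated-region genes were higher as a list (median 1.59, 6 of 6 positive, 3 called over all genes and 3 within the list, adjusted p = 1.9e-05). Chemokine receptors and homing genes were higher, with Ccr1, Cxcr4, Cxcr6 and Gpr15 called, 4 by either adjustment (median 0.96, 16 of 19 positive, adjusted p = 0.0015), at 0.61 without scurfy mock array 1. Treg surface molecules had 22 of 26 positive members, 0 called over all genes, and 5 higher and 1 lower within the list (median 0.61, adjusted p = 0.17). All 21 interferon-induced genes were positive, with 0 called by either adjustment (median 1.53, adjusted p = 8.8e-05). Without scurfy mock array 1 the median was 0.43 and the call ended, and without scurfy mock array 2 it was 2.72. In that array the list had a mean of 9.88, against 7.14 in scurfy mock array 2. TCR-induced early genes were lower (median -0.45, 16 of 24 negative, adjusted p = 8.8e-05). The median was 0.13 and not called without scurfy mock array 1, -0.91 without scurfy mock array 2 and -0.72 after quantile normalization. Th17 genes were higher (median 1.17, Rora called, adjusted p = 0.021), a call that ended without scurfy mock array 2 (0.98) or Tconv mock array 1 (1.01). Amino acid stress genes were called lower by camera although their median was 0.01 (adjusted p = 0.041), and the median was -0.25 after quantile normalization, where the call ended. It was 0.09 without scurfy mock array 2 and 0.08 without Tconv mock array 2, and neither was called. It was -0.29 without scurfy mock array 1 and -0.20 without Tconv mock array 1. Phgdh, the first enzyme of serine synthesis, was the called member (-2.19, SE 0.29). Amino acid stress genes lost theirs at a common 75th percentile (-0.28) and without a filter (0.0076), and stood at -0.17 with each probe set. Th17 genes lost theirs with a pseudocount of 64 (0.58) and when filtered at the 75th percentile (1.32). Leaving out the 2 least correlated arrays ended the calls of TCR-induced early (0.13) and interferon-induced genes (0.45), and put homing genes at 0.61. TCR-induced early genes stood at -0.74 at a common 75th percentile, -0.25 with a pseudocount of 64 and -0.28 with each probe set. With an estimated correlation the adjusted p was 0.784 for interferon-induced genes and 0.761 for each other called list.

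limma called 65 genes, 50 higher and 15 lower, among 1562 at an unadjusted p under 0.05, all 65 with groups that did not overlap, against 50.9% of all genes. The common 75th percentile gave 75 calls (50 higher, 25 lower). There were 5 calls without Tconv mock array 1, 10 without Tconv mock array 2, 25 without scurfy mock array 1, 30 without either Tconv Foxp3 array and 232 without scurfy mock array 2. Ikzf2, Cxcr6, Foxp3, Flicr and Dgkk, 5 of 25 named called genes, kept the call in all 10 leave-one-out fits.

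Tconv Foxp3 against Tconv mock asked what set arrays labelled Foxp3-transduced apart from mock arrays in cells without the Treg starting state. Higher genes were Ipcef1 (4.56, SE 0.42, adjusted p = 0.0099), the co-inhibitory receptor Cd160 (3.27, SE 0.40), the transcription factor Tox (2.65, SE 0.34), Qser1 (2.35, SE 0.29), Kbtbd8 (1.95, SE 0.25) and the heparan sulfate sulfotransferase Hs3st3b1 (1.90, SE 0.26). Lower genes were Grp (-5.32, SE 0.68), the nuclear receptor Pparg (-3.91, SE 0.36, adjusted p = 0.0099), Lgals3, which encodes galectin-3 (-3.66, SE 0.43), and the immediate early gene Ier3 (-3.65, SE 0.40). Il10 (-4.13, SE 0.64, adjusted p = 0.080), Ebi3 (-3.53, SE 0.64, adjusted p = 0.14), Il2 (3.39, SE 0.86, adjusted p = 0.19), Ctla4 (-1.15, SE 0.39, adjusted p = 0.28), Ikzf2 (0.51, SE 0.30) and Il2ra (-0.30, SE 0.24) were not called.

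The single Foxp3 probe set did not rise in the arrays labelled Foxp3-transduced. Its intensity was 18.0 and 18.9 in Tconv Foxp3, 53.9 and 35.9 in Tconv mock, 948 and 691 in scurfy Foxp3, 1188 and 1114 in scurfy mock, and 2130 and 3128 in Treg. The difference between Foxp3 and mock was -0.80 in Tconv (SE 0.30, adjusted p = 0.31, 95% interval -1.49 to -0.12) and -0.50 in scurfy cells (SE 0.30, adjusted p = 0.999, 95% interval -1.18 to 0.18). The probe set's position in the transcript was not given.

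Th2 genes fell in Tconv Foxp3, with 13 of 14 negative, 0 called over all genes and 3 lower within the list (median -1.64, adjusted p = 4.8e-12). The median was -2.72 without Tconv mock array 1 and -1.03 without Tconv mock array 2, and the Tconv mock arrays differed in Il5 (48.2 and 1871) and Il13 (230 and 5773). Treg surface molecules also fell, with 18 of 26 negative, 0 called and 4 lower within the list (median -0.33, adjusted p = 9.0e-09). This median was -0.75 without Tconv mock array 2, -0.11 without Tconv mock array 1, -0.62 and -0.14 without Tconv Foxp3 arrays 1 and 2, and -0.56 after quantile normalization. Amino acid stress genes fell with 0 called by either adjustment (median -0.25, 11 of 16 negative, adjusted p = 0.00011), at -0.51 after quantile normalization, -0.38 without Tconv Foxp3 array 1 and -0.14 without Tconv Foxp3 array 2. Demethylated-region genes were lower (median -0.30, 5 of 6 negative, adjusted p = 0.010), a call that ended without Tconv Foxp3 array 2 (-0.21) or Tconv mock array 1 (-0.20). Its median was -0.47 without Tconv mock array 2, -0.50 after quantile normalization and -0.18 with each probe set. At a common 75th percentile the medians were -0.61 for Treg surface molecules, -0.59 for demethylated-region genes and -0.54 for amino acid stress genes. With an estimated correlation the adjusted p was 0.738 for demethylated-region genes and 0.371 for the others here.

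In Tconv Foxp3, effector T cell cytokines (median -0.24, adjusted p = 0.0016, adjusted p = 0.807 with an estimated correlation) lost the call under quantile normalization (-0.55), under the common 75th percentile (-0.53), without Tconv Foxp3 array 1 (-0.05) and without Tconv mock array 2 (0.48). Their median was -0.61 without scurfy Foxp3 array 1 or Treg array 2, -0.44 without Tconv Foxp3 array 2 and -0.93 without Tconv mock array 1. Cell cycle genes were higher, with 27 of 29 positive (median 0.43, adjusted p = 0.045, adjusted p = 0.812 with an estimated correlation). That call ended under the common 75th percentile (0.15) and without either scurfy mock array (0.43), either Treg array (0.43), either Tconv mock array (0.48) or Tconv Foxp3 array 2 (0.29). It ended as well when filtered at the 75th percentile (0.42). Th1 and cytotoxic genes (median -0.13, adjusted p = 0.048, adjusted p = 0.371 with an estimated correlation) were not called in 7 leave-one-out fits, with 0.16 without Tconv Foxp3 array 2, -0.02 without Tconv mock array 1, -0.34 without Tconv mock array 2 and -0.13 without each scurfy array. They were at -0.24 without Tconv Foxp3 array 1 and -0.40, not called, after quantile normalization. The Th1 and cytotoxic call also ended at a common 75th percentile (-0.42), without a filter (0.035), and at -0.13 with a pseudocount of 1, array weights or without the 2 least correlated arrays. It held at -0.52 when filtered at the 75th percentile and at 0.093 with each probe set. Myeloid cell markers (median -0.22, adjusted p = 0.035, adjusted p = 0.738 with an estimated correlation) lost the call under quantile normalization (-0.32), without Tconv Foxp3 array 1 (-0.07), Tconv mock array 1 (-0.01) or scurfy mock array 1 (-0.22), and stood at -0.38 without Tconv mock array 2. They also lost it at a common 75th percentile (-0.51) and when filtered there (-0.38). B cell markers had 10 of 11 positive members (median 0.98, adjusted p = 0.081).

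limma called 10 genes, 6 higher and 4 lower, among 1577 at an unadjusted p under 0.05, all 10 with groups that did not overlap, against 59.2% of all genes. Quantile normalization called 6 (1 higher, 5 lower) and the common 75th percentile 7 (2 higher, 5 lower). There were 0 calls without Tconv Foxp3 array 2 or Tconv mock array 2, 1 without Tconv mock array 1, 3 without either scurfy Foxp3 array, 5 without either Treg array, and 19 and 18 without a scurfy mock array. None of the 10 kept its call in all 10 leave-one-out fits, and weighting the arrays raised the count to 527.

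Scurfy Foxp3 against scurfy mock asked what set the same labels apart in cells with an active Foxp3 promoter. The higher genes were Cxcl16, the ligand of CXCR6 (2.55, SE 0.29), Pxdc1 (2.39, SE 0.27), Clec4n, the lectin receptor Dectin-2 of myeloid cells (2.32, SE 0.26), and Mmp13, a collagenase (2.23, SE 0.25), each at adjusted p = 0.029. Foxp3 (-0.50, SE 0.30), Ikzf2 (0.02, SE 0.30), Ctla4 (0.15, SE 0.39), Il2ra (0.13, SE 0.24) and Nt5e (1.38, SE 0.31, adjusted p = 0.61) were not called.

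B cell and myeloid markers were higher in scurfy Foxp3. All 11 B cell markers were positive, with 0 called over all genes and 3 higher within the list (median 1.27, adjusted p = 1.1e-08, adjusted p = 0.388 with an estimated correlation). The median was 0.50 without scurfy mock array 1 and 2.00 without scurfy mock array 2. Without the 2 least correlated arrays it was 0.60 and not called, and it was 2.52 with a pseudocount of 1, 0.56 with 64 and 3.68 when filtered at the 75th percentile. Ighm, the heavy chain of immunoglobulin M, had 505 and 2921 in scurfy Foxp3 and 19.2 and 65.4 in scurfy mock (4.53, SE 1.08, adjusted p = 0.61). Cd79a, part of the B cell receptor, had 302 and 933 against 4.50 and 73.5 (3.68, SE 0.90, adjusted p = 0.63). All 8 myeloid markers were positive, with 0 called over all genes and 4 higher within the list (median 0.85, adjusted p = 2.9e-07, adjusted p = 0.388 with an estimated correlation). Tyrobp, the signalling adaptor DAP12, had 284 and 383 against 13.3 and 39.5 (3.10, SE 0.45, adjusted p = 0.11). The myeloid median was 1.41 with a pseudocount of 1, 0.38 with 64, 0.16 without a filter and 1.61 when filtered at the 75th percentile.

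Early activation and lipid lists moved with scurfy mock array 1. All 24 TCR-induced early genes were positive, with 0 called by either adjustment (median 0.71, adjusted p = 2.7e-09). Without that array the median was 0.09 and not called, and without scurfy mock array 2 it was 1.17. Cholesterol synthesis genes were lower, with 14 of 15 negative and 0 called by either adjustment (median -0.94, adjusted p = 1.1e-08). Without it the median was -0.24 and not called, and without its replicate -1.61. Effector T cell cytokines were higher, with 15 of 17 positive, 0 called and 1 higher within the list (median 1.17, adjusted p = 1.3e-05). Their median was 0.04 and not called without it, and 2.02 without its replicate. Treg surface molecules were higher (median 0.24, 22 of 26 positive, 0 called and 1 higher within the list, adjusted p = 0.0082), a call that ended without scurfy mock array 1 (0.14) or scurfy Foxp3 array 2 (0.39). Co-inhibitory receptors (median 0.60, adjusted p = 0.0082) were at -0.16 without scurfy mock array 1 and lost the call without scurfy Foxp3 array 1 (0.36), with 1.37 without scurfy mock array 2. Glycolysis genes (median -0.21, adjusted p = 0.0082) lost the call without scurfy mock array 1 (-0.07) or scurfy Foxp3 array 1 (-0.39). They were at -0.03 without scurfy Foxp3 array 2 and -0.41 without scurfy mock array 2, called in both. Leaving out the 2 least correlated arrays ended the calls of TCR-induced early genes (0.18), cytokines (0.39), Treg surface molecules (0.35), co-inhibitory receptors (0.061) and glycolysis genes (0.070), and moved cholesterol synthesis genes to -0.081. Adjusted p with an estimated correlation was 0.388 for TCR-induced early genes, 0.559 for Treg surface molecules and glycolysis genes, and 0.438 for the other lists here.

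Of the red blood cell markers 2 were measured (median -0.94, adjusted p = 0.023, adjusted p = 0.388 with an estimated correlation), and the call ended without scurfy mock array 1 (-0.30) or scurfy Foxp3 array 1 (-1.28), with -0.61 without scurfy Foxp3 array 2 and -1.59 without scurfy mock array 2. It ended too without a filter (-0.067) and without the 2 least correlated arrays (0.038). Of the mast cell and basophil markers 2 were measured (median 0.96, adjusted p = 0.042, adjusted p = 0.388 with an estimated correlation), and the call ended under quantile normalization (0.97) and without scurfy Foxp3 array 1 (0.99), scurfy Foxp3 array 2 (0.93) or scurfy mock array 2 (0.65). The mast cell call also ended at a common 75th percentile (0.99), with a pseudocount of 64 (0.50), without a filter (-0.011), with the mean of probe sets (0.67) and without the 2 least correlated arrays (1.24). Th17 genes (median 0.23, adjusted p = 0.0499, adjusted p = 0.559 with an estimated correlation) lost the call under quantile normalization (0.26) and without scurfy Foxp3 array 2 (0.62), scurfy mock array 1 (0.39) or either Tconv Foxp3 array (0.23). It was 1.18 without scurfy mock array 2 and 0.64 without either Tconv mock array. The Th17 call ended too with a pseudocount of 1 (1.38), when filtered at the 75th percentile (0.73), with each probe set (0.012) and without the 2 least correlated arrays (0.57). Heat shock genes (median 0.22, adjusted p = 0.067), CD8 T cell markers (median -0.88, adjusted p = 0.067), pan T cell genes (median -0.13, adjusted p = 0.21) and sex-linked genes (median 0.40, adjusted p = 0.25) were not called here or in any other comparison. limma called 4 genes in all, 4 higher and 0 lower, among 481 at an unadjusted p under 0.05, and their groups did not overlap, as for 22.8% of all genes. The count was 50 without scurfy mock array 2 and 0 without any other array, and 0 with a pseudocount of 1, with array weights and without the 2 least correlated arrays. It was also 0 with each probe set on its own, with trend and robust options and in a fit on the compared groups alone.

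The difference of the differences asked whether Foxp3-labelled arrays departed alike from mock in scurfy and conventional cells. limma called 0 genes, with 911 at an unadjusted p under 0.05 and a smallest adjusted p of 0.213. Il10, the anti-inflammatory cytokine, had a difference of 5.30 (SE 0.90, adjusted p = 0.21), Ier3 of 3.85 (SE 0.57, adjusted p = 0.21), Ebi3 of 3.66 (SE 0.91, adjusted p = 0.44) and Cd160 of -2.89 (SE 0.57, adjusted p = 0.26), so the changes in Cd160 and Ier3, called in Tconv, were not shown to differ between the kinds of cell. Without scurfy mock array 2 there were 28 calls and without Tconv Foxp3 array 1 there was 1. As lists, Th2 genes (median 2.22, 13 of 14 positive, 1 higher within the list, adjusted p = 4.5e-11, adjusted p = 0.236 with an estimated correlation) and Treg surface molecules (median 0.89, 21 of 26 positive, 2 higher within the list, adjusted p = 4.5e-11, adjusted p = 0.286 with an estimated correlation) were higher in the scurfy effect. The Th2 median was 1.45 without Tconv Foxp3 array 2 and 1.41 without Tconv mock array 2, and that of the Treg molecules 0.40 without Tconv mock array 1. Follicular helper genes (median 0.85, adjusted p = 0.0079, adjusted p = 0.401 with an estimated correlation) were at -0.72 without scurfy mock array 1, and lost the call at 0.82 without scurfy Foxp3 array 2. They were at -0.35 and not called without the 2 least correlated arrays.

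Scurfy Foxp3 against Treg asked how close scurfy arrays labelled Foxp3-transduced stood to natural Treg. Higher in scurfy Foxp3 were the kinase gene Mapk10 (3.93, SE 0.44, adjusted p = 0.011), the metalloproteinases Mmp12 (3.32, SE 0.38) and Mmp13 (2.38, SE 0.25), Cxcr6 (3.07, SE 0.40) and its ligand Cxcl16 (2.09, SE 0.29). Lower were the transcription factor gene Tead1 (-3.81, SE 0.41), Cpe (-3.39, SE 0.31), lactoferrin (Ltf, -3.31, SE 0.34), Nt5e (-2.93, SE 0.31) and Flicr (-2.43, SE 0.30). Foxp3 (-1.65, SE 0.30, adjusted p = 0.085), Ikzf2 (-0.03, SE 0.30), Ikzf4 (-0.05, SE 0.29) and Ctla4 (0.20, SE 0.39) were not called.

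Effector cytokines were higher in scurfy Foxp3 than in Treg, with 16 of 17 positive, 0 called over all genes and 8 higher within the list (median 2.01, adjusted p = 9.1e-08). Th2 genes were higher, with 13 of 14 positive, 0 called and 8 higher within the list (median 1.45, adjusted p = 1.3e-06), with 0.97 without Treg array 1. Among their members, Il13 (6.39, SE 1.29, adjusted p = 0.12) and Ifng (4.33, SE 0.85, adjusted p = 0.12) were not called. Amino acid stress genes were higher, with 0 called, and 7 higher and 1 lower within the list (median 0.75, adjusted p = 2.0e-05). Interferon-induced genes were higher with 18 of 21 positive and 0 called by either adjustment (median 1.48, adjusted p = 0.00011). Their median was 0.55 without Treg array 1 and 0.78 without scurfy Foxp3 array 1. The 8 myeloid markers were all positive, 0 called and 2 higher within the list (median 0.71, adjusted p = 2.0e-05), and B cell markers were higher (median 1.23, adjusted p = 0.0073), a call that ended without scurfy Foxp3 array 2 (1.17) or Treg array 1 (0.54), with 1.97 without Treg array 2. Naive and memory T cell genes were lower (median -0.76, adjusted p = 0.00044), a call that ended without scurfy Foxp3 array 1 (-0.83), with -0.37 without Treg array 2. Th1 and cytotoxic genes (median 1.03, adjusted p = 0.016) lost theirs without scurfy Foxp3 array 2 (0.88) or Treg array 2 (0.36), with 0.63 without Treg array 1. Th17 genes (median 0.33, adjusted p = 0.032) lost theirs without scurfy Foxp3 array 2 (0.98) or Treg array 1 (0.27), with 0.95 without Treg array 2. The Th17 call also ended at a common 75th percentile (0.39), with a pseudocount of 1 (0.42), with the mean of probe sets (0.25) and without the 2 least correlated arrays (0.98). Th1 and cytotoxic genes lost theirs at a common 75th percentile (1.09) and without the 2 least correlated arrays (0.88), as did B cell markers without the latter (1.17). Adjusted p with an estimated correlation was 0.432 for cytokines and naive and memory genes, 0.918 for interferon-induced genes and B cell markers, 0.697 for Th17 genes and 0.298 for the other called lists.

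Treg surface molecules had 14 of 26 positive members against Treg, with Nt5e called lower by either adjustment (median 0.10, adjusted p = 0.96). limma called 20 genes, 11 higher and 9 lower, among 1004 at an unadjusted p under 0.05, all 20 with groups that did not overlap, against 31.4% of all genes. There were 0 calls without scurfy Foxp3 array 1 or Treg array 1, 1 without scurfy Foxp3 array 2, 11 without either Tconv Foxp3 array and 42 without either scurfy mock array, so 0 of the 18 named called genes kept the call in all 10 leave-one-out fits. Quantile normalization gave 40 calls, a pseudocount of 1 gave 0, and leaving out the 2 least correlated arrays gave 6.

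Scurfy mock against Treg asked how scurfy cells labelled mock differed from natural Treg. Lower in scurfy mock were Cpe (-4.50, SE 0.31, adjusted p = 0.0012), Nt5e (-4.30, SE 0.31, adjusted p = 0.0012), Tox (-3.37, SE 0.34), Ipcef1 (-3.74, SE 0.42), the integrin subunit Itgb8 (-3.70, SE 0.45) and Gad1 (-3.69, SE 0.37). Higher were Mmp10 (3.74, SE 0.49) and Cxcr6 (3.12, SE 0.40). Foxp3 (-1.16, SE 0.30, adjusted p = 0.24), Ikzf2 (-0.05, SE 0.30) and Ikzf4 (-0.01, SE 0.29) were not called. Th2 genes were higher, with 11 of 14 positive, 0 called, and 5 higher and 1 lower within the list (median 0.94, adjusted p = 0.0003, adjusted p = 0.693 with an estimated correlation). Naive and memory T cell genes were lower, with 14 of 17 negative, 0 called, and 1 higher and 5 lower within the list (median -0.81, adjusted p = 0.00058, adjusted p = 0.693 with an estimated correlation). That median was -0.25 without scurfy mock array 2, -1.23 without Treg array 1 and -0.28 without Treg array 2, and the Th2 median was 1.42 without Treg array 2.

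Against Treg, interferon-induced genes (median 1.41, adjusted p = 2.4e-05) were at -0.07 without scurfy mock array 1, cholesterol synthesis genes (0.69, adjusted p = 0.0001) at 0.10, TCR-induced early genes (-0.42, adjusted p = 0.0025) at 0.15, glycolysis genes (0.32, adjusted p = 0.0069) at 0.13, amino acid stress genes (0.60, adjusted p = 0.0025) at 0.40 and Th1 and cytotoxic genes (0.45, adjusted p = 0.021) at 0.67, none of them called without it. Each of these lists, and effector T cell cytokines (0.84, adjusted p = 0.047), had an adjusted p = 0.693 with an estimated correlation. Without Treg array 2 the glycolysis (0.22), amino acid stress (0.33), Th1 and cytotoxic (0.54) and cytokine (1.18) calls also ended, without Treg array 1 the TCR-induced early call (-0.54), and without either scurfy Foxp3 array the Th1 and cytotoxic (0.45) and cytokine (1.17 and 0.84) calls. Without scurfy mock array 2 the cytokine median was -0.0026 and the call ended, as it did under quantile normalization (0.97), at a common 75th percentile (0.87), with a pseudocount of 1 (0.81) and with array weights (0.84). Leaving out the 2 least correlated arrays ended the calls of the 6 lists that ended without scurfy mock array 1. Calls that held moved without scurfy mock array 2 for interferon-induced (2.52), cholesterol synthesis (1.40), TCR-induced early (-0.87) and Th1 and cytotoxic genes (0.94). They also moved without scurfy mock array 1 for cytokines (1.69), and without Treg arrays 1 and 2 for interferon-induced genes (0.52 and 2.21). limma called 29 genes, 8 higher and 21 lower, among 897 at an unadjusted p under 0.05, all 29 with groups that did not overlap, against 32.4% of all genes. Quantile normalization called 59 (28 higher, 31 lower) and the common 75th percentile 58 (27 higher, 31 lower). There were 2 calls without Treg array 1, 7 without Treg array 2, 4 without scurfy mock array 1, 9 and 15 without a Tconv Foxp3 array and 68 without scurfy mock array 2. A fit on the compared groups alone gave 0, and Cpe and Nt5e kept theirs in all 10 leave-one-out fits.

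Tconv Foxp3 against Treg asked how conventional cells labelled Foxp3-transduced differed from natural Treg. Lower were Cpe (-6.53, SE 0.31, adjusted p = 2.2e-05), Ikzf2 (-6.24, SE 0.30, adjusted p = 2.2e-05), Foxp3 (-6.24, SE 0.30, adjusted p = 2.2e-05), Flicr (-4.77, SE 0.30), Nt5e (-4.87, SE 0.31), Ikzf4 (-2.69, SE 0.29) and Klrg1 (-3.71, SE 0.56). The interleukin 18 receptor gene Il18r1 (-4.07, SE 0.50) and Cxcr6 (-2.97, SE 0.40) were lower too. Higher were Dgkk (3.76, SE 0.50), Hs3st3b1 (3.18, SE 0.26, adjusted p = 0.0010), the signalling lymphocyte molecule Slamf7 (2.88, SE 0.47) and the growth factor Csf1 (2.76, SE 0.40). Ctla4 (-1.90, SE 0.39, adjusted p = 0.083), Il10 (-2.89, SE 0.64, adjusted p = 0.096) and Il2 (3.39, SE 0.86, adjusted p = 0.14) were not called.

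Treg surface molecules were lower, with 23 of 26 negative, Klrg1 and Nt5e called over all genes and 14 lower within the list (median -1.44, adjusted p = 1.5e-14). Demethylated-region genes were lower, with 6 of 6 negative, 3 called and 4 within the list (median -2.30, adjusted p = 6.5e-11). Chemokine receptors and homing genes were lower, with 2 called, and 1 higher and 10 lower within the list (median -1.11, adjusted p = 1.7e-07), at -0.73 without Treg array 2. All 29 cell cycle genes were positive, with 0 called by either adjustment (median 0.46, 0.29 after quantile normalization, adjusted p = 0.00031). So were all 15 cholesterol synthesis genes (median 0.70, adjusted p = 0.00044), whose call ended without Tconv Foxp3 array 1 (0.46). Th17 genes were lower (median -0.84, Rora and Ltb4r1 called, adjusted p = 0.0062), not called without Treg array 2 (-0.45) or when filtered at the 75th percentile (0.49). Myeloid markers were lower (median -0.55, adjusted p = 0.015), not called under quantile normalization (-0.38), without Treg array 2 (-0.13) or without Tconv Foxp3 array 1 (-0.49), with -0.89 without Treg array 1. The myeloid call also ended without a filter (-0.10) and when filtered at the 75th percentile (-0.60). Treg-related transcription factors were called lower with a median of -0.05 (adjusted p = 0.048), Foxp3, Ikzf2 and Ikzf4 being the called members, and lost the call without each scurfy array (-0.05), Treg array 1 (-0.18) or Tconv Foxp3 array 2 (-0.23). Their median was 0.12 without Treg array 2 and 0.18 without Tconv Foxp3 array 1, although camera still gave the call downward. The transcription factor call also ended without a filter (-0.05), with the mean of probe sets (-0.03), with each probe set (0.082), and at -0.05 with array weights, on the compared groups alone and without the 2 least correlated arrays. Adjusted p with an estimated correlation was 0.79 for cell cycle, 0.735 for Th17 and 0.752 for cholesterol synthesis genes and the transcription factors, 0.747 for myeloid markers and 0.167 for the first 3 lists.

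limma called 76 genes, 16 higher and 60 lower, among 1549 at an unadjusted p under 0.05, all 76 with groups that did not overlap, against 49.8% of all genes. There were 6 calls without Tconv Foxp3 array 2, 8 without Treg array 2, 14 without Tconv Foxp3 array 1, 48 without Treg array 1, 50 without either scurfy Foxp3 array and 115 without either scurfy mock array. Hs3st3b1, Cpe, Ikzf2, Foxp3, Nt5e and Flicr, 6 of 26 named called genes, kept the call in all 10 leave-one-out fits, and quantile normalization gave 121 calls.

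Scurfy Foxp3 against Tconv Foxp3 compared, under the Foxp3 label, starting cells that differed inseparably in strain and GFP. Higher in scurfy Foxp3 were Ikzf2 (6.22, SE 0.30, adjusted p = 5.8e-05), Cxcr6 (6.03, SE 0.40), Il1r2 (5.50, SE 0.45), Foxp3 (4.58, SE 0.30) and Ikzf4 (2.64, SE 0.29). Il10 (4.91, SE 0.64, adjusted p = 0.0078) and Ebi3 (4.04, SE 0.64, adjusted p = 0.018) were higher. Both fell, not called, in Tconv Foxp3 against mock. Also higher were Entpd1 (CD39, 3.93, SE 0.58), Nt5e (1.94, SE 0.31), Ctla4 (2.10, SE 0.39, adjusted p = 0.036) and the checkpoint receptor Havcr2 (3.87, SE 0.54). Lower were Il2, the growth factor of T cells (-4.28, SE 0.86, adjusted p = 0.042), Hs3st3b1 (-3.75, SE 0.26), Ipcef1 (-3.22, SE 0.42) and the early gene Egr3 (-3.12, SE 0.55). Without any single array of the 4 compared, Ctla4 and Il2 lost the call, and Il10 did so without scurfy Foxp3 array 2 or Tconv Foxp3 array 2.

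Treg surface molecules were higher, with 24 of 26 positive, 10 called over all genes (Ccr8, Ctla4, Ebi3, Entpd1, Fgl2, Icos, Il10, Klrg1, Nt5e and Penk) and 15 within the list (median 1.48, adjusted p = 3.4e-12). Demethylated-region genes were higher, with 6 of 6 positive and 4 called by either adjustment (median 2.37, adjusted p = 7.0e-09). Th2 genes were higher, with 12 of 14 positive, 3 called, and 9 higher and 1 lower within the list (median 2.39, adjusted p = 1.3e-06). Chemokine receptors and homing genes were higher, with 5 called, and 8 higher and 1 lower within the list (median 1.38, adjusted p = 1.7e-05), at 0.83 without scurfy Foxp3 array 1. Th17 genes were higher with 2 called and 5 within the list (median 1.76, adjusted p = 5.8e-06). Interferon-induced genes were higher with Xaf1 called and 4 higher within the list (median 1.60, adjusted p = 5.0e-06). Myeloid markers were also higher, Fcer1g and Tyrobp being called and 6 within the list (median 1.73, adjusted p = 2.3e-07). Adjusted p with an estimated correlation was 0.184 for Th2 genes, 0.515 for interferon-induced genes and 0.145 for the other lists here.

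Among the remaining lists of this comparison, effector T cell cytokines were higher, with Il10 called higher, Il2 called lower, and 8 higher and 1 lower within the list (median 1.40, adjusted p = 6.9e-05, adjusted p = 0.442 with an estimated correlation), at 2.21 without scurfy Foxp3 array 2. All 15 cholesterol synthesis genes were negative, with 0 called and 1 lower within the list (median -0.94, adjusted p = 6.9e-05, adjusted p = 0.515 with an estimated correlation), at -0.61 without Tconv Foxp3 array 1. Without scurfy Foxp3 array 2 the calls ended for Treg-related transcription factors (median 0.09, 0.29 without it, adjusted p = 0.0047, adjusted p = 0.421 with an estimated correlation), Th1 and cytotoxic genes (1.26, 1.24 without it, adjusted p = 0.0059, adjusted p = 0.145 with an estimated correlation) and cell cycle genes (-0.31, -0.02 without it, adjusted p = 0.010, adjusted p = 0.689 with an estimated correlation), the last also without Tconv Foxp3 array 2 (-0.19). Medians also moved to -0.58 for cell cycle genes and 0.14 for the transcription factors without scurfy Foxp3 array 1, and to 0.57 and 0.25 for Th1 and cytotoxic genes and the transcription factors without Tconv Foxp3 array 2. B cell markers (median 0.56, adjusted p = 0.028, adjusted p = 0.634 with an estimated correlation) were not called under quantile normalization (0.51), without scurfy Foxp3 array 2 (0.73) or without Tconv Foxp3 array 1 (0.63), with 0.87 without Tconv Foxp3 array 2. That B cell call also ended with a pseudocount of 1 (0.76) and the mean of probe sets (0.53), and stood at 2.47 when filtered at the 75th percentile. Of the NK cell markers 4 were measured (median 2.49, adjusted p = 0.041, adjusted p = 0.425 with an estimated correlation), not called under quantile normalization (2.42), without either scurfy Foxp3 array (2.06 and 2.71), either scurfy mock array (2.49) or Tconv Foxp3 array 2 (1.70). The NK call also ended at a common 75th percentile (2.52), with a pseudocount of 1 (3.36), without a filter (0.33), when filtered at the 75th percentile (2.93) and with array weights (2.49). Leaving out the 2 least correlated arrays ended the calls of the transcription factors (0.29), Th1 and cytotoxic genes (1.24), cell cycle genes (-0.02), B cell markers (0.73) and NK cell markers (2.71).

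limma called 254 genes, 185 higher and 69 lower, among 1938 at an unadjusted p under 0.05, all 254 with groups that did not overlap, against 48.4% of all genes. There were 9 calls without Tconv Foxp3 array 2, 36 without Tconv Foxp3 array 1 and 37 without scurfy Foxp3 array 2. Without scurfy Foxp3 array 1 there were 241, of which 70 were higher and 171 lower, and 91 of them were among the 254. Ikzf2, Cxcr6, Il1r2, Foxp3 and Hs3st3b1, 5 of 43 named called genes, kept the call in all 10 leave-one-out fits.

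**Figure D2:**
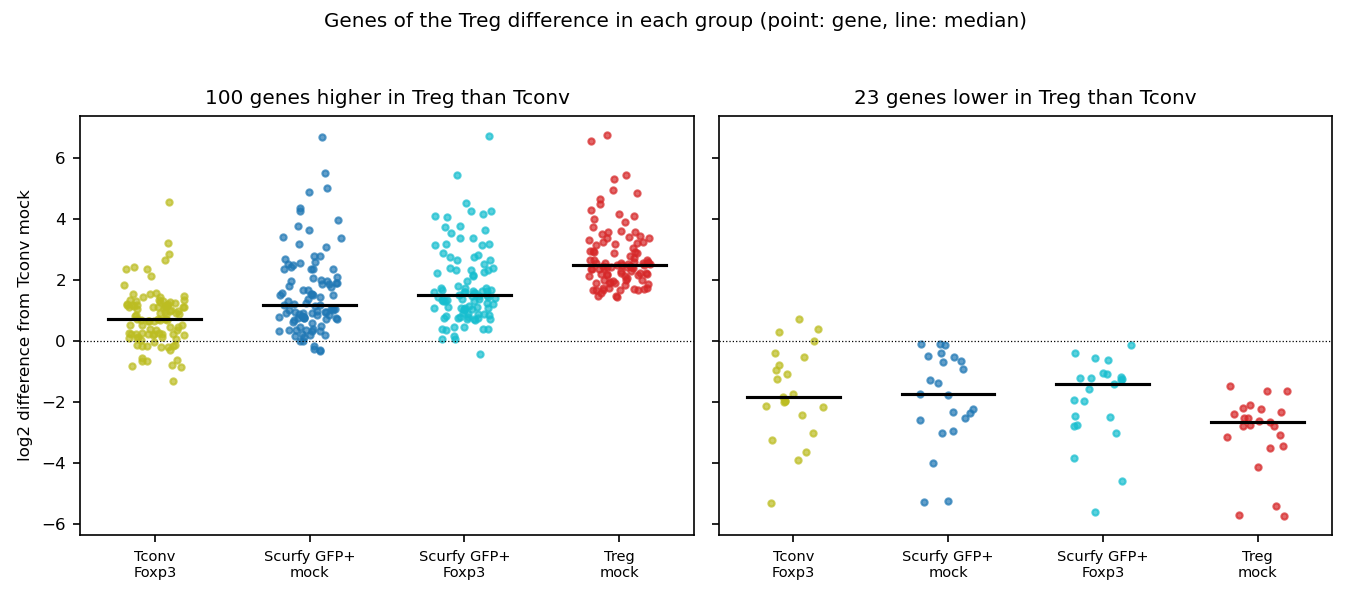
Log2 difference from Tconv mock, on the vertical axis, of the 100 genes called higher and the 23 called lower in Treg, shown for Tconv Foxp3, scurfy mock, scurfy Foxp3 and Treg. Points are genes and lines are medians, which for the higher genes were 0.73 in Tconv Foxp3, 1.18 in scurfy mock and 1.52 in scurfy Foxp3.

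The genes called in Treg were followed through the other groups. Relative to Tconv mock, the 100 higher genes had a median of 1.18 in scurfy mock, 0.73 in Tconv Foxp3 and 1.52 in scurfy Foxp3, and 25, 3 and 33 of them were called higher. The 23 lower genes had medians of -1.74, -1.84 and -1.40, with 8, 3 and 7 called lower. These groups share the Tconv mock arrays with the Treg comparison, so part of these medians comes from how the genes were chosen. In unchanged simulated groups sharing gave a correlation across genes of 0.50, no baseline for groups that differ. Measured ones were 0.63 for scurfy mock, 0.48 for Tconv Foxp3 and 0.62 for scurfy Foxp3, and 33, 6 and 40 genes were called in the same direction. From Treg itself, 16 of the 100 higher genes differed in scurfy mock, 37 in Tconv Foxp3 and 10 in scurfy Foxp3.

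Comparisons that use none of the Treg or Tconv mock arrays gave 6 tests. In scurfy Foxp3 against Tconv Foxp3, the 100 higher genes were higher with a median of 0.73, 77 positive, 27 called higher and 2 lower (camera p = 8.7e-17, adjusted p = 5.2e-16, adjusted p = 0.228 with an estimated correlation). In scurfy mock against Tconv Foxp3 the median was 0.41, with 65 positive, 22 called higher and 3 lower (camera p = 6.2e-09, adjusted p = 1.8e-08, adjusted p = 0.324 with an estimated correlation). In scurfy Foxp3 against scurfy mock the median was 0.22, with 64 positive and 1 called higher (camera p = 8.5e-06, adjusted p = 1.7e-05, adjusted p = 0.390 with an estimated correlation). That call ended without scurfy mock array 2 (median -0.04), and without scurfy Foxp3 array 1 the median was -0.05 although camera still called the genes higher. In that comparison the median was 0.38 without scurfy mock array 1 or Tconv Foxp3 array 1, 0.36 without Tconv Foxp3 array 2, 0.33 and 0.69 without a Tconv mock array and 0.52 without Treg array 2. Each of these fits called its own Treg genes, so the sets differ from the 100. Without Treg array 2, where 12 genes were called higher in Treg, the first 2 medians were 2.28 and 1.86. The first was 1.47 without Tconv mock array 2, and the second 0.76 without scurfy mock array 2. The third median was 0.12 under quantile normalization, at a common 75th percentile and with each probe set, and 0.11 with array weights. It was 0.38 without a filter, 0.35 on the compared groups alone and 0.44 without the 2 least correlated arrays, called in each. On the compared groups alone the first was 1.61 and the second 0.75. The second was also 0.85 with a pseudocount of 1, 0.19 with 64, 0.62 when filtered at the 75th percentile and 0.20 with the mean of probe sets. The 23 lower genes had medians of -0.25, 0.06 and -0.11 in these comparisons (adjusted p = 0.437, 0.747 and 0.437), and in the second of them camera gave a downward direction.

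**Figure D3:**
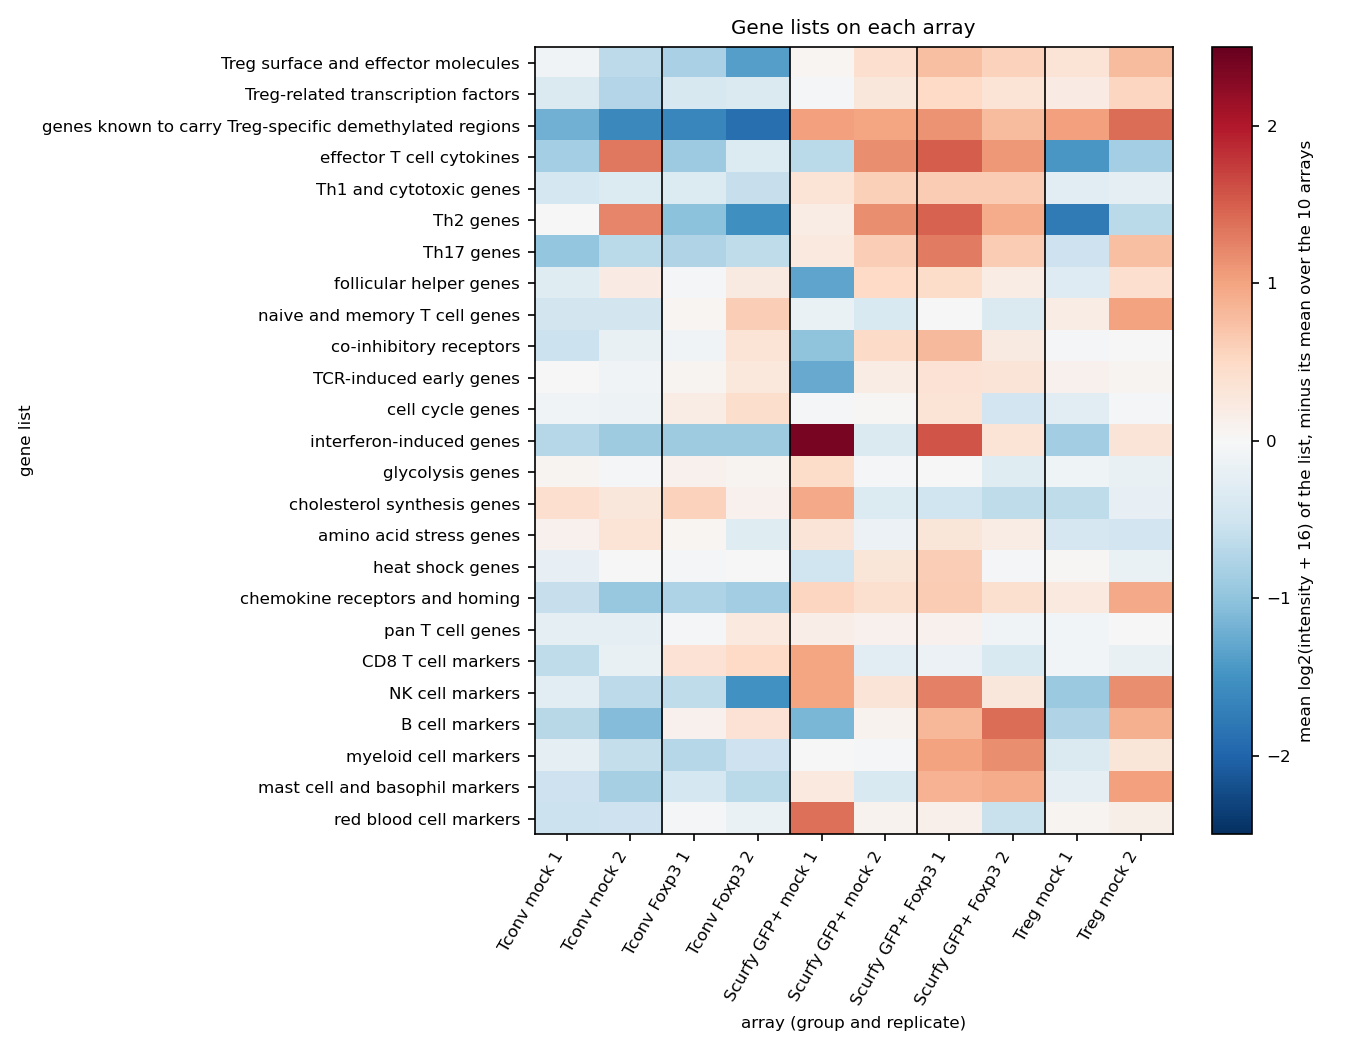
Heat map of gene lists in rows and the 10 arrays in columns, with color for the list's mean log2(intensity + 16) minus its mean over all arrays. Interferon-induced genes were highest on scurfy mock array 1, with a mean of 9.88 against 7.14 in its replicate, and on scurfy Foxp3 array 1, with 9.08 against 7.84.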

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

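For the B cell, class II and myeloid genes below, the class II and below-filter tests were chosen before the result was seen, and the tests in conventional T cells only afterwards.

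Several gene lists differed between Foxp3-labelled and mock arrays otherwise in scurfy than in conventional cells, although limma called 0 single genes for that difference (smallest adjusted p = 0.213, 911 genes at an unadjusted p under 0.05). The median difference was 2.22 for Th2 genes, 1.49 for effector T cell cytokines and 0.89 for Treg surface and effector molecules. It was 1.25 for myeloid markers and 0.68 for amino acid stress genes. These 5 lists kept the call without each array, with medians from 1.41 to 2.65 for Th2 genes, 0.56 to 3.32 for cytokines, 0.40 to 1.05 for the Treg molecules, 1.03 to 1.45 for myeloid markers and 0.30 to 0.77 for amino acid stress genes. By camera their adjusted p was 4.5e-11, 1.9e-08, 4.5e-11, 6.9e-09 and 1.4e-05. Cytokines were at 2.25 with a pseudocount of 1 and 0.58 without the 2 least correlated arrays. Amino acid stress genes were at 1.03 under quantile normalization, 0.36 with the mean of probe sets and 0.18 with each probe set. Myeloid markers were at 0.76 with a pseudocount of 64, 0.53 without a filter and 1.99 when filtered at the 75th percentile. With an estimated correlation the adjusted p was 0.236, 0.365, 0.286, 0.236 and 0.303, so none was called.

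Other lists depended on single arrays. TCR-induced early genes had a median of 0.74 (adjusted p = 1.5e-06, adjusted p = 0.401 with an estimated correlation), and -0.15 without scurfy mock array 1. Follicular helper genes had 0.85, and -0.72 without that array. Cholesterol synthesis genes had -0.78 (adjusted p = 0.012, adjusted p = 0.524 with an estimated correlation), not called without scurfy mock array 1 (-0.24), scurfy Foxp3 array 1 (-0.96) or Tconv Foxp3 array 1 (-0.59). B cell markers had 0.20 (adjusted p = 0.043, adjusted p = 0.524 with an estimated correlation), and -0.62 without scurfy mock array 1. That B cell call also ended under quantile normalization (0.24) and without scurfy Foxp3 array 2 (0.43), Treg array 1 (0.20), Tconv Foxp3 array 1 (-0.10) or Tconv mock array 1 (0.08). It ended too at a common 75th percentile (0.52), with a pseudocount of 1 (0.17), without a filter (0.24) and with the mean of probe sets (-0.20). Leaving out the 2 least correlated arrays ended the calls of TCR-induced early (-0.28), follicular helper (-0.35) and cholesterol synthesis genes (-0.15) and of B cell markers (-0.36). Cholesterol synthesis genes were at -0.50 under quantile normalization and -0.46 at a common 75th percentile.

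Among probe sets without a gene symbol, 39 were called between Treg and Tconv mock, 36 higher and 3 lower, of 3715 tested.

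B cell, class II and myeloid genes were higher in scurfy Foxp3 than in scurfy mock. Cells of other types among the sorted cells would be one source. The 4 class II genes measured had a median difference of 3.51 (1.48 and 5.54 without scurfy mock arrays 1 and 2). Such cells would bring this, although the sorts for CD4 and NGFR should have removed them. An effect of the Foxp3 virus in any starting cell stays open too. In Tconv Foxp3 against Tconv mock, B cell markers had a median of 0.98 and class II genes 3.25. Yet mock replicates differed as much in class II genes, by 4.06 (scurfy) and 3.77 (Treg), though by -0.42 in Tconv. Myeloid markers leave both sources undecided. Their median in Tconv Foxp3 against mock was -0.22, with Fcer1g and Tyrobp near background. Those below the filter had 0.088 in scurfy cells (10 of 14 positive). Flow cytometry or single-cell data could separate these sources.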

How the results depend on the processing

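Omitting the 2 least correlated arrays was chosen after seeing the data. With 2 arrays per group and 1 variance per gene over all groups, counts depend on every array kept, compared or not. Other causes were untested. No named gene turned its called direction in any alternative.

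Quantile normalization gave 6 called genes for Foxp3 against mock in Tconv, 40 for scurfy Foxp3 against Treg, 59 for scurfy mock against Treg and 121 for Tconv Foxp3 against Treg, and the carried lower Treg genes had a median of -0.29 in scurfy Foxp3 against Tconv Foxp3. The common 75th percentile gave 43, 58 and 123 in the comparisons with Treg, and lower Treg genes at -0.10 in scurfy Foxp3 against mock and -0.32 against Tconv Foxp3. A pseudocount of 1 gave 56 for Treg and 35 for scurfy mock against Tconv mock, 0 for the Foxp3 label in scurfy cells, 0, 6 and 48 for scurfy Foxp3, scurfy mock and Tconv Foxp3 against Treg, and 106 for scurfy Foxp3 against Tconv Foxp3. A pseudocount of 64 gave 41 for scurfy mock against Tconv mock.

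Without a filter the counts were 57 for Treg and 28 for scurfy mock against Tconv mock, 3 for the Foxp3 label in Tconv, 16 and 35 for scurfy mock and Tconv Foxp3 against Treg, and 123 for scurfy Foxp3 against Tconv Foxp3, with lower Treg genes at -0.16 in scurfy mock against Tconv Foxp3. The filter at the 75th percentile gave 2 for the Foxp3 label in scurfy cells and 13 for scurfy Foxp3 against Treg. The mean of probe sets gave 5 for the Foxp3 label in Tconv. Each probe set on its own gave 281 for Treg, 5 and 0 for the Foxp3 label in Tconv and scurfy cells, and 52 and 145 for scurfy mock and Tconv Foxp3 against Treg.

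The trend and robust fit gave 193 for Treg, 106 for scurfy mock, 0 for the Foxp3 label in scurfy cells, 1 for the difference of the effects, and 36 and 51 for scurfy Foxp3 and scurfy mock against Treg. Array weights gave 219 for Treg, 527 and 0 for the Foxp3 label in Tconv and scurfy cells, 9, 17 and 133 for scurfy Foxp3, scurfy mock and Tconv Foxp3 against Treg, and 118 for scurfy Foxp3 against Tconv Foxp3, with lower Treg genes at -0.29 there. Fits on the compared groups alone gave 34 for Treg, 1 for scurfy mock, 27 and 0 for the Foxp3 label in Tconv and scurfy cells, 39 and 0 for scurfy Foxp3 and scurfy mock against Treg, and 430 for scurfy Foxp3 against Tconv Foxp3.

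With a replicate block the counts were 81 for Treg, 42 for scurfy mock, 0 for the Foxp3 label in scurfy cells, 9 and 50 for scurfy mock and Tconv Foxp3 against Treg, and 165 for scurfy Foxp3 against Tconv Foxp3. Calls ended for cell cycle (0.43) and Th1 and cytotoxic genes (-0.13) in Tconv and for amino acid stress genes (0.01) in scurfy mock against Tconv mock. Deviations of replicates from their group means were not shared between groups (r across genes from -0.17 to 0.18, and genes are not independent replicates).

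Without the 2 least correlated arrays the counts were 34 for scurfy mock against Tconv mock, 6 and 0 for the Foxp3 label in Tconv and scurfy cells, 6 and 10 for scurfy Foxp3 and scurfy mock against Treg, and 116 for scurfy Foxp3 against Tconv Foxp3. Lower Treg genes were at -0.063 in scurfy Foxp3 against mock. Directions turned in scurfy Foxp3 against mock for Treg surface molecules (0.35), co-inhibitory receptors (0.061), TCR-induced early genes (0.18) and interferon-induced genes (1.34). They also turned for B cell markers in the difference of the effects (-0.36), and in scurfy mock against Treg for TCR-induced early (0.15) and interferon-induced genes (-0.069). The direction is that of camera and can differ from the sign of the median given.

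Leaving out single arrays gave counts from 17 to 217 for Treg, 5 to 232 for scurfy mock, 0 to 19 and 0 to 50 for the Foxp3 label in Tconv and scurfy cells, and 0 to 28 for the difference. They ran from 0 to 42, 2 to 68 and 6 to 115 for scurfy Foxp3, scurfy mock and Tconv Foxp3 against Treg, and from 9 to 375 for scurfy Foxp3 against Tconv Foxp3. With the Treg genes called anew in each fit, the higher ones ran from -0.053 to 0.69 in scurfy Foxp3 against mock, 0.63 to 2.28 in scurfy Foxp3 and 0.27 to 1.86 in scurfy mock against Tconv Foxp3. Lower Treg genes ran from -0.45 to 0.41, -0.66 to 1.85 and -0.77 to 1.87.

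Directions turned without scurfy Foxp3 array 1 for cell cycle genes in scurfy Foxp3 against mock (-0.26, up to 0.36 without scurfy Foxp3 array 2). They turned without scurfy mock array 1 for co-inhibitory receptors in scurfy mock against Tconv mock (0.77, down to -0.43 without other arrays) and in scurfy Foxp3 against mock (-0.16, up to 1.37), for interferon-induced genes in scurfy Foxp3 against mock (1.00, down to -1.25) and scurfy mock against Treg (-0.069, up to 2.52), for TCR-induced early genes there (0.15, down to -0.87), and for lower Treg genes in scurfy mock against Tconv Foxp3 (0.35). They turned without scurfy mock array 2 for lower Treg genes in scurfy Foxp3 against mock (0.41), interferon-induced genes in the difference (-0.99, up to 1.22) and cytokines in scurfy mock against Treg (-0.0026, up to 1.69). Without Treg array 2 lower Treg genes turned in scurfy Foxp3 (1.85) and scurfy mock (1.87) against Tconv Foxp3.

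Of 959 named gene results, 14 were stronger and 16 weaker under quantile normalization, 2 and 95 with a pseudocount of 1, 0 and 76 without a filter, 37 and 72 on the compared groups alone, and 35 and 8 with trend and robust options. Of 234 list results, 6 were stronger and 12 weaker under quantile normalization, and 4 and 26 without the 2 least correlated arrays.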

Other observations

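For the Foxp3 probe set and for strain variants beside Foxp3, the tests were chosen only after the result was seen, and the window test was chosen before.

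Class II genes, which present antigen on B cells and myeloid cells, differed between replicates of some groups. H2-Aa had 0.397 and 412 in the scurfy mock arrays, 1114 and 1685 in scurfy Foxp3, 47.6 and 723 in Treg, 213 and 308 in Tconv Foxp3, and 8.29 and 10.6 in Tconv mock. Cd74, the invariant chain of class II, had 48.6 and 870, 2041 and 3207, 91.9 and 1711, 439 and 421, and 51.4 and 25.8 in the same order. The median of the class II genes on array 2 minus array 1 was 4.06 in scurfy mock and 3.77 in Treg, against -0.42 in Tconv mock, 0.39 in Tconv Foxp3 and 0.41 in scurfy Foxp3. Between scurfy Foxp3 and scurfy mock, H2-Aa had 4.05 (SE 1.41), H2-Eb1 3.59 (SE 1.5), Cd74 3.43 (SE 1.33) and H2-Ab1 0.97 (SE 0.39), none of them called (limma adjusted p = 0.999).

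Th2 cytokines also split replicates. Il5 was 53.0 and 1351 in scurfy mock, 1653 and 1139 in scurfy Foxp3, 11.5 and 13.7 in Tconv Foxp3 and 48.2 and 1871 in Tconv mock. In Treg it was 2.97 and 5.41. Il4 was 308 and 4093 in scurfy mock and 51.4 and 2037 in Tconv mock, so in these groups array 2 carried the higher Th2 cytokines. In Treg the Th2 list had a mean of 7.23 on array 1 and 8.32 on array 2.

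Of 10 measured genes beside Foxp3 on the X chromosome, 4 were called higher in Treg than in Tconv mock. Syp had 4.87 (SE 0.68), Usp27x 2.59 (SE 0.33), Ccdc22 2.48 (SE 0.27) and Ppp1r3f 2.24 (SE 0.34), while Dgkk, further away, was called lower at -5.72. Clcn5 (0.33), Plp2 (0.24), Gpkow (0.53), Wdr45 (0.90) and 2010204K13Rik (1.11) were not called. In scurfy Foxp3 against Tconv Foxp3, 3.35% of windows of 10 neighbouring genes had as high a median (0.40). Only scurfy cells carry the scurfy allele, so this leaves chance in Treg undecided. Strain variants with that allele are argued against only by the labels, by which Treg and Tconv mock lack it. The 40% of neighbours called higher restates the pattern and adds no support. It replaced a test on their median (1.01) after its value was seen. Gene order came without coordinates, and whether the Foxp3 locus acts on its neighbours stays open.

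No Tconv array showed a raised Foxp3 probe set, the highest being 2.53% of the lowest Treg array. This would speak against exchanged mock and Foxp3 labels only if the probe set detects viral Foxp3. The larger change in Foxp3-labelled arrays was -0.50, as a virus lacking the probed part, or no Foxp3 virus, would allow. In Tconv Foxp3, Treg surface molecules (-0.33) and demethylated-region genes (-0.30) fell, as an exchange could give, but Th2 genes (-1.64) fell as in Treg. An exchange and the missing rise stay open until probe positions or vector sequence are compared.

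The Treg profile in scurfy mock cells was compared through the shared Tconv mock arrays, which may give part of the excess. The covariance with the Treg difference was 0.286 against 0.107 in simulation for scurfy mock, 0.201 against 0.107 for Tconv Foxp3 and 0.302 against 0.106 for scurfy Foxp3. Independent lists of these sizes would share 0.472, 0.0611 and 0.945 genes. With 2 control arrays they could not be split. In scurfy mock against Tconv Foxp3, which shares no arrays with the Treg comparison, the 100 higher genes had a median of 0.41 with 65 positive (camera adjusted p = 1.8e-08, adjusted p = 0.324 with an estimated correlation). In scurfy Foxp3 against Tconv Foxp3 it was 0.73 (adjusted p = 5.2e-16, adjusted p = 0.228 with an estimated correlation). Without Treg array 2 these medians were 1.86 and 2.28 over the 12 genes then called higher in Treg.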
